A study of Rattus norvegicus with 33 samples.

How the data were processed

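Gene expression was compared between carrageenan-treated and control rats on 2-colour oligonucleotide microarrays printed to order with probes for neurotransmitter receptors and transporters, neuropeptides, neurotrophins, cytokines and their receptors. Carrageenan is a seaweed polysaccharide that causes local inflammation. Per the labels' protocols, pups received 0.25% carrageenan at 1 µl per g of body weight in the plantar skin of the left hindpaw on postnatal day 3 or on postnatal day 12, and tissue was taken from male adults at postnatal day 60. Per the labels' protocols, total RNA was isolated with TRIzol, and 5 µg per sample was reverse transcribed with a 3DNA Array Detection Kit whose primers carry different capture sequences for control and treated tissue. Per the labels, the carrageenan sample carried one Alexa dye and the control sample the other on every array, and no dye swap is named. The 33 arrays fall into 6 groups by age of injection (P3 or P12) and tissue: left or right side of the lumbar spinal dorsal horn (LDH), or brain. The P3 groups had 6 arrays each and the P12 groups 5. The labels do not say which arrays came from rats with a second inflammation as adults, so all arrays of a group were analysed together.

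The deposited values were read as log2 ratios of the 2 channels, with 1 table per age. The deposited tables state neither the log base nor the direction of the ratio, and the scanner, background correction and normalization are not given in the sources used here. The values are signed, array medians lay between 0 and 0.0855, and the largest absolute value was 6.43. That value is a ratio of 86.3 if the base is 2, of 621 if it is the natural base, and of 2697740 if it is 10. The last lies beyond the 65535 steps of a 16-bit scanner, and a natural base is not excluded. The test results do not depend on the base. The direction is likely carrageenan over control, since carrageenan is channel 1 in the labels, but this is not stated, so only positive and negative log ratios are given. Arrays of an age correlated weakly (median r = 0.160 at P3 and 0.241 at P12, near-identical pairs left out), and P3 LDH left array 4 had the lowest mean correlation with its table, 0.0244, so these values cannot show whether the channels of an array were exchanged.

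Array annotation gave 1 gene symbol to 196 of 222 probes at P3 and to 205 of 232 probes at P12. The other 26 and 27 probes were unnamed here, were tested, and are counted without a name. Entrez identifiers of 187 and 195 probes were found in the rat gene table used for current names, which changed 0 symbols. The other named probes kept the array's name, and some of these carry human or mouse sequence entries (IL12A, IL12B, PPYR1, Il16, Il7r, Ntsr1). Probes of one symbol were averaged within an array, which gave 158 symbols at each age and 184 tested items at P3 and 185 at P12. Of the symbols, 23 at P3 and 30 at P12 had several probes.

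P3 LDH left arrays 5 and 6 correlated at r = 0.969 over probes, and 92.3% of their values lay within 0.1 of each other. P3 LDH right arrays 1 and 2 correlated at r = 0.806, with 65.8% of values within 0.1. No other pair of P3 arrays correlated above 0.417 and no pair of P12 arrays above 0.553. Each of these 2 pairs was averaged and counted as 1 sample, a choice made after the data were seen, so P3 LDH left and right each had n = 5. These averages are called P3 LDH left replicate 5 and P3 LDH right replicate 1. Nothing in the labels says that the arrays of a group came from separate animals, so p-values measure the spread between these samples only. Replicate numbers were not taken to pair samples across tissues.

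For each group, the mean log ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all items of the table). A gene passed at an adjusted p under 0.05. Within an age, the difference between LDH left and right and that between LDH (mean of both sides) and brain were tested the same way. Arrays were used as deposited because array medians spanned less than 0.3. The 2 ages were run on different platforms and stand in 2 tables whose normalization is not given. Ages were thus set side by side without a test, and age and platform cannot be told apart. Of 20 gene lists fixed before the data were examined, 12 had at least 3 genes and were tested with camera (preset correlation 0.01, and with an estimated correlation) and with fry. Lists of glial, neuronal and blood cell markers, reference genes, dopamine receptors and other growth factors had 0 genes among the named probes. The list of histamine and acetylcholine receptors held histamine receptors only, and that of neuropeptide Y, galanin and somatostatin held no galanin gene, so they are named here by what they held. Glutamate transporters and the list of tumour necrosis factor, interferon and chemokine genes had 2 genes each and were not tested.

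The genes named were set by a rule fixed before the data were examined. For each test against 0, up to 10 passing genes with the largest positive and up to 10 with the largest negative mean were named, and where fewer than 6 passed, those with the smallest p were added up to 6. For each difference, up to 5 passing genes each way were named, or the 2 with the smallest p where none passed. The 15 measured genes of a pain-related panel were reported in the cord in addition, whatever their values. A probe without a gene name was counted and not named. Genes named outside the rule are marked as such.

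The tests were tried on simulated data with the spread of the real genes and 12 genes changed by each of 3 sizes. In P12 LDH right the test recovered 32.5% of genes changed by 0.5 log units, 60.5% of those changed by 1 and 90.7% of those changed by 2, with 4.01% of all calls false. In P3 LDH left, among 184 items, it recovered 71.3% of genes changed by 1. The simulated noise was drawn independently for each gene, and the recovered shares can be lower where fewer genes change. The alternatives tried were centring, testing each probe, leaving out genes with an exact 0 on any array, 1 fit for all tissues of an age, a plain one-sample test, robust variance and regression, array weights, replicate blocks, scaling, and leaving out each sample. Signal intensities were not used here, so faint spots could not be identified. The number of arrays limits the precision of every mean.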

Results

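The data were 33 two-channel arrays from adult rats that had received carrageenan in the left hindpaw as pups, each read against control tissue. In 18 arrays the injection was on postnatal day 3 (P3), inside a sensitive period named by the study, and in 15 on postnatal day 12 (P12), outside it. Tissue came from the left (injected side) or right lumbar spinal dorsal horn (LDH), the first relay of pain signals in the cord, or from brain. Values are log ratios of the 2 channels, read as log2, whose base and direction the sources used here do not state, so signs are given as deposited. The SD of the log ratios within an array ranged from 0.353 to 1.17 at P3 and from 0.326 to 1.20 at P12. For 17 sequence entries with several probes at P12, the mean log ratios over tissues correlated at r = -0.0092 between probes of one entry, and for 8 such entries at P3 at r = -0.14, so each value is given as that of its probes.

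The first comparison asked which genes differed from control in the left cord after injection at P3. No gene passed. The smallest p belonged to Gabrp, a GABA receptor subunit, with a mean log ratio of -0.92 ± 0.42 (SD, n = 5), negative in 5 of 5 samples. Ntrk2, the receptor of brain-derived neurotrophic factor, had 0.42 ± 0.17 and was positive in 5 of 5 samples, and each of these 2 genes had an adjusted p of 0.334. Htr5b, a serotonin receptor, had 0.26 ± 0.091, and Il10ra, a receptor chain for an anti-inflammatory cytokine, had -0.22 ± 0.059. Il7r, a cytokine receptor on a mouse sequence entry, had 0.48 ± 0.36 with 1 sample at exactly 0, and the kainate receptor subunit Grik2 had 0.54 ± 0.44, positive in 4 of 5. The limma count of passing genes was 0 of 184, with 10 at an unadjusted p under 0.05 where chance gives 9.2, and the plain one-sample test and robust regression also gave 0. Ntrk2 turned to -0.13 when the mean of the other 2 tissues was subtracted.

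Among the gene groups of P3 LDH left, the GABA receptors had 7 positive and 7 negative means among 14 genes, and Gabrp passed when adjusted over the list alone. The neurotrophins and their receptors also had 1 gene, Ntrk2, that passed when adjusted over the list alone, and Bdnf lay at -0.77 ± 0.66, negative in 5 of 5 samples with an adjusted p of 0.606. For these 6 genes, fry's test for change in either direction gave an adjusted p of 0.0225. Glutamate receptors had 13 positive and 9 negative means, and interleukins and receptors 21 and 14. None of the 12 lists passed camera, with the preset or with an estimated correlation. GABA synthesis and transport genes were all positive (4 of 4), and the serotonin, adrenergic and neuropeptide Y and somatostatin lists had 9 of 15, 5 of 8 and 9 of 11 positive means. The 15 measured genes of the pain-related panel had means from -0.77 (Bdnf) to 0.17 (Npy), with the opioid receptor Oprm1 at -0.02 ± 0.61, proenkephalin Penk at -0.25 ± 0.34 and the substance P precursor Tac1 at 0.10 ± 0.23, and 0 passed. The other panel means were -0.14 for Oprd1, -0.15 for Oprk1, 0.0071 for Pdyn, 0.16 for Calca, 0.051 for Grin1, -0.37 for Grin2b, 0.016 for Il1b, -0.010 for Il6, -0.12 for Sst and -0.14 for Gabbr1.

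In the right cord after injection at P3, the uninjected side, no gene passed. The metabotropic glutamate receptor Grm5 had -1.68 ± 0.83 and was negative in 5 of 5 samples, with an adjusted p of 0.226. IL12B, a cytokine subunit on a human sequence entry, had 1.48 ± 0.84 and was positive in 5 of 5. The neurotrophin Ntf4 had -0.40 ± 0.22, the GABA receptor subunits Gabrq and Gabrg3 had -0.33 ± 0.15 and 0.35 ± 0.18, and the neuropeptide Y receptor Npy1r had 0.62 ± 0.42. All 6 had the same sign in 5 of 5 samples. The limma count was 0 of 184, with 17 at an unadjusted p under 0.05, the plain one-sample test gave 0 and robust regression 3, with IL12B among them. Grm5 turned to 0.38 when the mean of the other 2 tissues was subtracted.

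By group, glutamate receptors of P3 LDH right had 18 positive and 4 negative means among 22 genes, and Grm5 passed when adjusted over the list alone. GABA receptors had 4 positive and 10 negative means, with a median of -0.087. For change in either direction, fry gave adjusted p values of 0.0151 (GABA receptors), 0.0206 (neurotrophins and their receptors) and 0.0341 (glutamate receptors). Fry's test for a shift one way passed no list. Camera passed none, with the preset (lowest adjusted p = 0.577) or an estimated correlation. The panel means ranged from -0.47 (Bdnf) to 0.39 (Oprk1), with Il6 at 0.20 ± 0.14 and Oprm1 at 0.10 ± 0.056, each positive in 5 of 5 samples, and 0 of 15 passed. Many panel means lay near 0, and their signs depended on the setting. The other panel means were -0.092 for Oprd1, -0.081 for Penk, -0.037 for Pdyn, -0.024 for Tac1, 0.060 for Calca, 0.069 for Grin1, -0.044 for Grin2b, -0.12 for Il1b, -0.13 for Npy, -0.023 for Sst and -0.075 for Gabbr1.

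In brain after injection at P3, Grm5 was the 1 gene that passed, with a mean log ratio of -2.05 ± 0.64 (SD, n = 6), an adjusted p of 0.0124 and a negative value in 6 of 6 samples. Its single probe ranged from -3.04 to -1.39. Bdnf lay at -0.82 ± 0.65, the inflammatory cytokine Il1b at -0.33 ± 0.18, the melanin-concentrating hormone receptor Mchr1 at 0.47 ± 0.33 and the somatostatin receptor entry SSTR at 0.24 ± 0.076. The histamine receptor Hrh4 lay at -0.52 ± 0.36, but its 2 probes had -1.57 and 0.53. These 5 genes had the same sign in 6 of 6 samples and an adjusted p of 0.299. The Grm5 call was lost without replicate 2, 4 or 5 (adjusted p = 0.0572, 0.0674 and 0.0801), in the plain one-sample test (0.0581), and in 1 fit with both cord groups (0.0656). With the cord mean subtracted, Grm5 in brain was -0.17.

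Among the groups of P3 brain, the glutamate receptors had 13 positive and 9 negative means with 1 passing gene, and fry's adjusted p for change in either direction was 0.0235. In the list of 4 histamine receptors, Hrh4, Hrh2 (0.24 ± 0.17) and Hrh1 (0.24 ± 0.18) passed when adjusted over the list alone; the last 2 were named after their values were seen. Camera passed 0 of 12 lists, with the preset (lowest adjusted p = 0.770) or an estimated correlation.

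Differences between tissues at P3 asked whether the ratios depended on the injected side or on cord against brain. Left and right cord differed at 0 of 184 items, with 5 at an unadjusted p under 0.05. Grik2 had 0.54 on the left and -0.25 on the right, a difference of 0.79 ± 0.30 (SE), and the glutamate receptor subunit Gria1 had -0.55 and 0.15, a difference of -0.70 ± 0.29, each with an adjusted p of 0.966. Between cord and brain 0 items passed, with 7 at an unadjusted p under 0.05. Grm8, a metabotropic glutamate receptor, had 0.75 and 0.40 in left and right cord and -0.41 in brain, a difference of 0.98 ± 0.33 (SE) with an adjusted p of 0.573, and Il1b differed by 0.28 ± 0.10 with an adjusted p of 0.756. In simulated data the left and right comparison found 66.5% of genes that differed by 1 log unit and 91.2% of those that differed by 2. No gene list passed camera or fry in either difference.

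After injection at P12, no gene passed in the left cord. The neurotrophin Ntf3 had -1.65 ± 0.93 (SD, n = 5), the cholecystokinin receptor Cckbr -1.39 ± 0.81, the neurokinin receptor Tacr3 -0.99 ± 0.53 and the GABA receptor subunit Gabra4 -1.59 ± 1.03, each negative in 5 of 5 samples with an adjusted p of 0.267. Il12a, a cytokine subunit, had 1.23 ± 0.88, and Vip, vasoactive intestinal peptide, 0.95 ± 0.68, both positive in 5 of 5. IL12A, the human sequence entry of the first, had -0.08 ± 0.54, negative in 3 of 5, and was named after its values were seen. The limma count was 0 of 185, with 24 at an unadjusted p under 0.05 where chance gives 9.25, 0 by the plain one-sample test and 1 by robust regression. The count was 9 in 1 fit with right cord and brain, where Ntf3, Cckbr, Tacr3, Gabra4, Il12a and Vip passed. Replicates 4 and 5, whose mean correlations with the other P12 arrays were 0.0843 and 0.0832, gave a count of 10 when both were left out, and without replicate 4 alone Ntf3 passed at -2.03 (adjusted p = 0.0433). Replicates 4 and 5 were picked for their low correlation, which favours agreement among the fewer samples left. The count of 10 is thus no support for a change.

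In the groups of P12 LDH left, the other neuropeptides and receptors had 8 negative means and 1 positive, Vip, among 9 genes, with a median of -0.22 and a fry adjusted p of 0.0410 for a shift one way. Camera, which sets the list against the other genes, gave it an adjusted p of 0.569, and 0.77 with an estimated correlation. Opioid peptides and receptors had 5 negative and 2 positive means (fry adjusted p = 0.0538). For change in either direction, fry passed 4 of 12 lists: neurotrophins and their receptors and adrenergic receptors and transporter (0.0219 each), and the tachykinin and CGRP family and other neuropeptides (0.0398 each), while camera passed 0 of 12, with the preset or an estimated correlation. Tacr3, Cckbr and Ntf3 each passed when adjusted over their own list alone. The panel means ranged from -0.49 (Oprm1) to 0.19 (Il1b), with the dynorphin precursor Pdyn at -0.46 ± 0.49 and Tac1 at -0.47 ± 0.41, and 0 of 15 passed. The other panel means were -0.36 for Oprd1, -0.16 for Oprk1, 0.046 for Penk, 0.17 for Calca, -0.21 for Grin1, 0.070 for Grin2b, 0.070 for Bdnf, -0.018 for Il6, 0.16 for Npy, -0.39 for Sst and -0.30 for Gabbr1.

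In the right cord after injection at P12, 7 of 185 items passed, 1 positive and 6 negative, and 1 of the negative items was an unnamed probe. Il2rb, a shared cytokine receptor chain, had a mean log ratio of -1.99 ± 0.22 (SD, n = 5) with an adjusted p of 0.000897, and Ntf3 had -2.58 ± 0.49 with an adjusted p of 0.00205. Cckbr had -1.52 ± 0.46, the chemokine receptor Cxcr1 -2.05 ± 0.73 and Npy1r -0.90 ± 0.33, with adjusted p values of 0.0182, 0.0225 and 0.0401. The kainate receptor subunit Grik1 was the positive gene at 0.91 ± 0.37 (adjusted p = 0.0438), and its 2 probes had 0.56 and 1.26. Each passing gene had the same sign in 5 of 5 samples, and 47 items had an unadjusted p under 0.05. Il2rb and Ntf3 passed whichever sample was left out, whereas the count fell to 2 without replicate 1 or 3, to 4 without replicate 2, and was 2 in the plain one-sample test. Grik1 lost its call without any 1 of the 5 samples (adjusted p from 0.0558 to 0.158), Npy1r without replicate 1, 2, 3 or 4, Cckbr without 1, 2 or 3 and Cxcr1 without 1 or 3. The count was 27 by robust regression (7 of 7 shared), 13 in 1 fit with the other tissues (4 of 7 shared), and 1, Ntf3, with the mean of left cord and brain subtracted.

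Among the groups of P12 LDH right, glutamate receptors had 14 positive and 8 negative means among 22 genes, with a median of 0.28 against 0.076 for other genes. Fry gave them an adjusted p of 0.0212 for a shift one way, and camera 0.616 (0.80 with an estimated correlation). The metabotropic receptors Grm3 and Grm8 lay at 0.80 ± 0.65 and 0.45 ± 0.33 without passing; the genes outside the panel in the rest of this paragraph were chosen after their values were seen. In the tachykinin and calcitonin gene-related peptide family, Tacr3 (-0.60 ± 0.22), Calcb (0.63 ± 0.32) and Calcrl (1.22 ± 1.00) passed when adjusted over the list alone, as did Hrh1 (0.75 ± 0.36), Hrh4 and Hrh2 in theirs. Fry found change in either direction in 11 of 12 lists, while camera passed 0 of 12, with the preset or an estimated correlation. In the panel, with means from -0.79 (Oprm1) to 0.42 (Oprk1), 0 of 15 genes passed. Il1b lay at 0.41 ± 0.13 and Oprm1 at -0.79 ± 0.61, each of one sign in 5 of 5 samples, with adjusted p values of 0.0763 and 0.124, and Il1b passed by robust regression (0.0207). Gabbr1, a GABA receptor, had -0.37 ± 0.26. The 7 probes of Gabbr1 had means from -1.69 to 0.86. The other panel means were -0.056 for Oprd1, -0.0075 for Penk, 0.26 for Pdyn, 0.18 for Tac1, 0.036 for Calca, -0.47 for Grin1, -0.0076 for Grin2b, -0.12 for Bdnf, 0.14 for Il6, 0.013 for Npy and -0.25 for Sst. Probes of one gene differed here too: those of Grin1 had 0.18, -2.02, 0.20 and -0.23, and those of Calca -0.28, -0.34 and 0.72.

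In brain after injection at P12, no gene passed. Cxcr1 had -1.57 ± 0.60 (SD, n = 5) with an adjusted p of 0.121, Il2rb -0.83 ± 0.54 and Tacr3 -0.59 ± 0.34, each negative in 5 of 5 samples, with the 2 Tacr3 probes at -0.02 and -1.17. The serotonin receptor Htr2c had -2.20 ± 1.31, negative in 4 of 5, and passed without replicate 4 at -2.76 with an adjusted p of 0.00558. The cytokine Il4 had 0.46 ± 0.17, with its 3 probes at 0.01, 0.73 and 0.65, and the GABA receptor subunit Gabrr1 0.55 ± 0.32, with 1 sample of Gabrr1 at exactly 0. The limma count was 0 of 185, with 31 at an unadjusted p under 0.05, 0 by the plain one-sample test and 11 by robust regression. With the cord mean subtracted, Cxcr1, Tacr3, Il2rb and Gabrr1 changed sign, to 0.22, 0.20, 1.10 and -0.40. Among the groups, the tachykinin and calcitonin gene-related peptide family had 5 positive and 2 negative means, and interleukins and receptors 22 and 13, and no list passed camera or fry.

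Between cord and brain at P12, Ntf3 and 1 unnamed probe passed among 185 items. Ntf3 had -1.65 ± 0.93 in left cord, -2.58 ± 0.49 in right cord and 0.51 ± 0.86 in brain (SD, n = 5 each), a difference of -2.63 ± 0.40 (SE) with an adjusted p of 0.00207. The highest adjusted p of Ntf3 with any 1 sample left out was 0.0088, and the gene has 1 probe. The unnamed probe had a difference of 0.99 ± 0.22 (SE) with an adjusted p of 0.0352, and lost its call without any 1 of 11 samples. With replicate number as a block, only 1 item passed. Between left and right cord 0 items passed, with 8 at an unadjusted p under 0.05: the cytokine Il2 had 0.82 on the left and -0.36 on the right, and Vip 0.95 and -0.02, each with an adjusted p of 0.686. In simulated data that comparison found 36.8% of genes differing by 1 log unit and 77.0% of those differing by 2. As at P3, these shares can be lower where fewer genes differ. No gene list passed camera or fry in either difference.

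**Figure D1:**
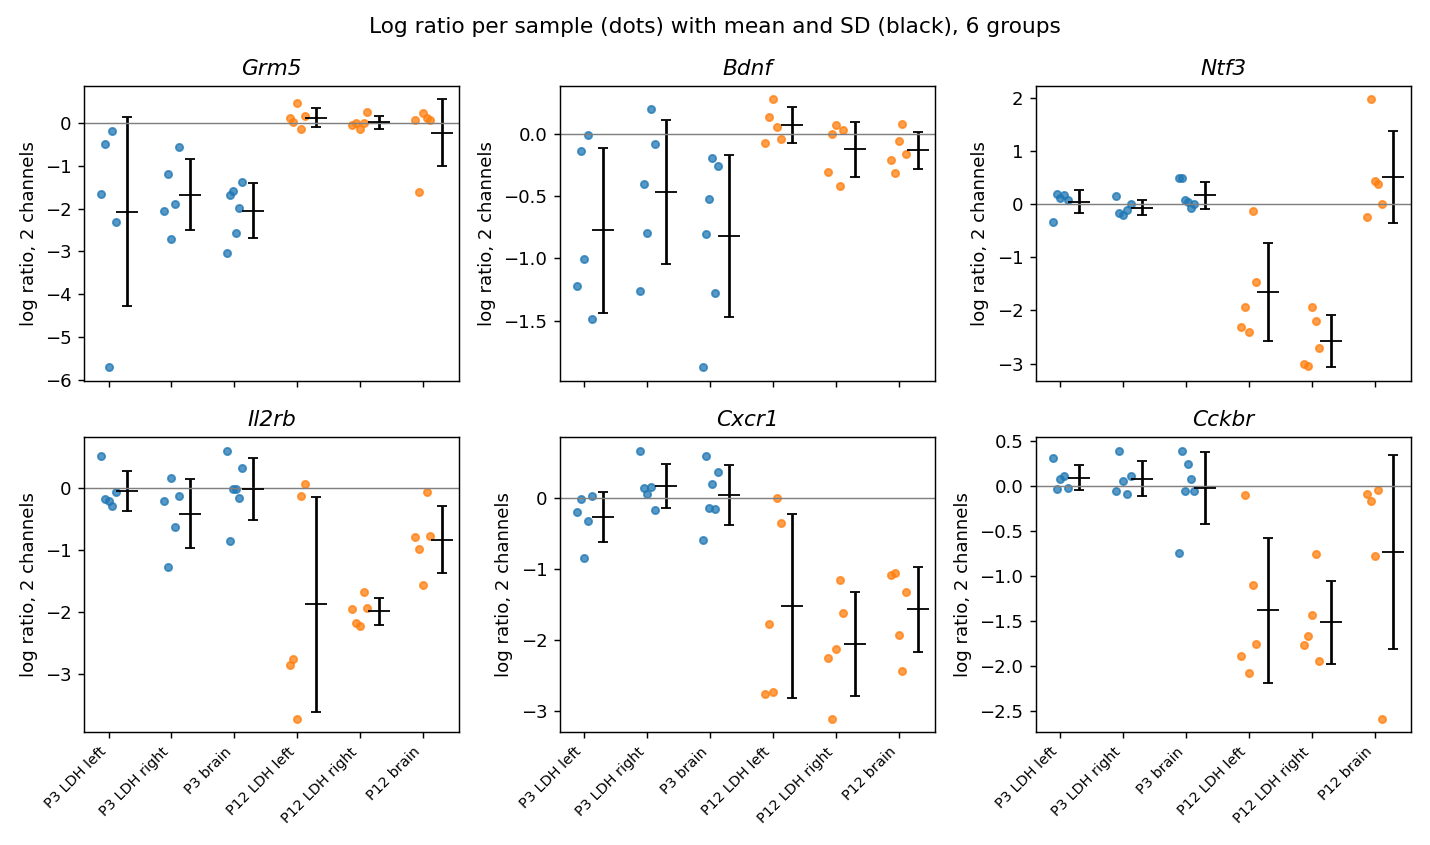
Log ratio of the 2 channels (log units as deposited, read as log2) of 6 genes in each sample of the 6 groups, with dots for samples and black marks for the mean and SD. The genes were picked after their values were seen, to show both ages: Grm5 is negative in every P3 sample, and Ntf3, Il2rb, Cxcr1 and Cckbr are negative in every sample of P12 LDH right.

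The study set injection at P3 against injection at P12, and here the ages stand side by side without a test. Grm5 had -2.07 ± 2.21, -1.68 ± 0.83 and -2.05 ± 0.64 in left cord, right cord and brain at P3, against 0.12, 0.01 and -0.23 at P12. Cxcr1 had -1.52 (4 of 5 negative, 1 at exactly 0), -2.05 and -1.57 at P12 against -0.27, 0.17 and 0.045 at P3. These 2 genes were picked after their values were seen. In the right cord, Npy1r was positive in all P3 samples (0.62) and negative in all P12 samples (-0.90). Its means in left cord and brain were negative at both ages (-0.18 and -0.35 at P3, -1.31 and -0.29 at P12). Across the 158 shared genes, which are not independent replicates, mean log ratios of 2 tissues of one age correlated at r = 0.46 to 0.68, and those of 2 groups of different age at 0.01 to 0.19. By rank the 2 ranges overlapped, with Spearman correlations of 0.247 to 0.50 within and 0.0447 to 0.302 across ages.

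**Figure D2:**
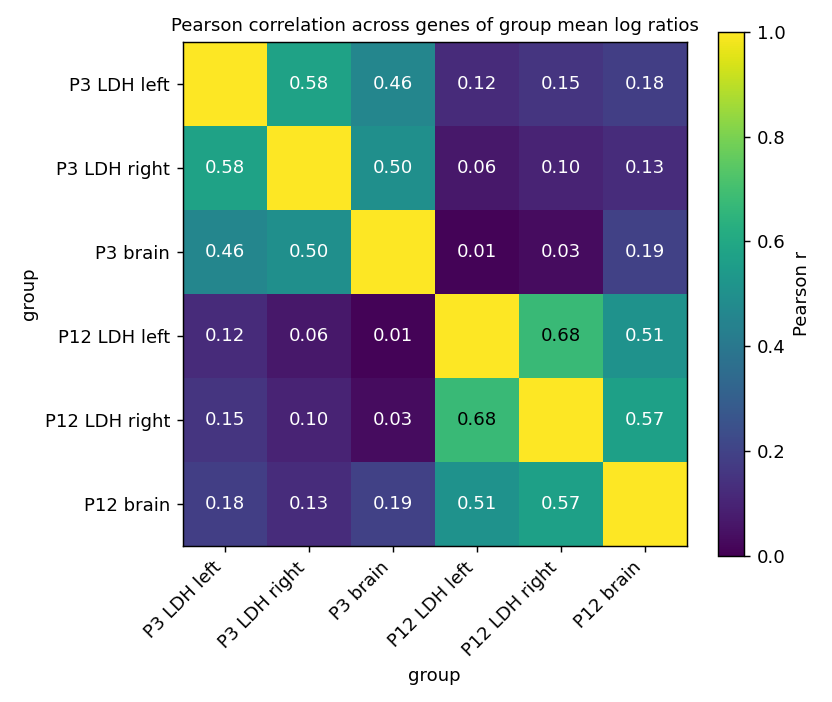
Pearson correlation across 158 genes (colour scale from 0 to 1) between the mean log ratios of each pair of the 6 groups, named on both axes. The pairs within P3 and within P12 lie at 0.46 or above and the pairs across ages at 0.19 or below. By rank (Spearman, not drawn) the ranges overlap: P3 left cord and brain lie at 0.247, below the highest pair across ages at 0.302. The other pairs within P3 lie at 0.330 and 0.347 and the pairs within P12 at 0.404 to 0.50.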

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

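The tests of the near-identical arrays and of Ntf3, and all counts of regrouped samples and exchanged channels, were set down after the results were seen.

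In P3 LDH left, single samples lay apart from the other 4 for Calca (0.60 against -0.06 to 0.10), Grin1 (0.40 against -0.12 to 0.02) and Npy (1.64 against -0.50 to 0.05). In P3 LDH right, replicate 5 had -0.25 for Pdyn against -0.0090 to 0.036, and in P12 LDH left, replicate 5 had 0.46 for Grin2b against -0.07 to 0.04. In P12 brain, replicate 2 had -1.63 for Grm5 (others 0.06 to 0.23), and replicate 5 had exactly 0 for Gabrr1 (others 0.56 to 0.74). In P3 brain, replicate 1 had an SD of log ratios over probes of 1.17, against 0.388 to 0.648 on the other 5 arrays. Chance alone gives about 1 such distance in 20 groups, which is 6.2 of the groups looked at, and 8 were found.

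P12 cord and brain differed in the Ntf3 log ratio by -2.63 (adjusted p = 0.00207, limma), and in 1 unnamed probe by 0.99 (adjusted p = 0.0352). Some genes had opposite signs in every sample of the 2 ages, and these differences were not tested: in right cord Npy1r had a mean of 0.62 at P3 and -0.90 at P12 and Oprm1 0.10 and -0.79, and in brain Il1b had -0.33 and 0.19. Of 158 genes, 0 were found in left cord, 2 in right cord and 1 in brain. Signs at random give 0.309 in each side of the cord and 0.154 in brain, but each group had more genes of one sign than that; at the rates found, unrelated ages give 1.48, 2.77 and 0.968, so the counts show no excess.

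In 2 pairs of P3 arrays the values were near-identical. The SD over probes of the difference was 0.123 for P3 LDH left arrays 5 and 6 and 0.317 for P3 LDH right arrays 1 and 2, against at least 0.443 for the other 151 pairs of P3 arrays. The pairs were picked for their likeness, so these values do not test whether one RNA pair or one hybridisation was entered as 2 arrays, and that stays open, as do a repeat hybridisation and a second scan. No biological explanation was tested.

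The lower Ntf3 log ratio of P12 cord than brain was weighed against dependence on 1 sample. With each of the 15 samples left out in turn the highest adjusted p was 0.0088, which argues against it. Other explanations that stay open are a property of the single probe, which reads exactly 0 on 1 brain array, and a difference between the tissues, both untested. Of 100 reassignments of the 15 samples, only 1, the real one, gave as many as 2 passing items, and the highest of the others gave 1. The share is under 0.05 for this count taken alone, without adjustment for the number of counts tested. With the replicate block or with scaled arrays the count is 1. Without genes with an exact 0 the count is also 1, but that filter removes Ntf3 itself, so the item left is not Ntf3. Samples were not reassigned under those settings. The second item, the unnamed probe, loses its call without any 1 of 11 samples.

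For the other counts, the samples were also regrouped or their channels exchanged. In P3 brain the real count of 1, by limma within the tissue, was reached in 1 of 32 exchanges of the channels (highest other 0). The share is under 0.05 for this count taken alone. It is the smallest these exchanges can give and was not adjusted for the number of counts tested. That gene, Grm5, did not pass in the plain one-sample test (adjusted p = 0.0581), in 1 fit with the other tissues (0.0656), with the mean of the other tissues subtracted (0.938), or without replicate 2 (0.0572), 4 (0.0674) or 5 (0.0801). With 5 samples there are only 16 exchanges, too few for a share under 0.05: the real and highest other counts were 7 and 0 in P12 LDH right, 0 and 0 in P3 LDH left, P12 LDH left and P12 brain, and 0 and 1 in P3 LDH right. For left against right cord at both ages and for cord against brain at P3 the real count was 0 (highest other 1). Every regrouping reaches a count of 0, here 100 of 100, so this says nothing about chance.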

How the results depend on the processing

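Merging the near-identical arrays, leaving out arrays of low correlation, the zero filter for differences between groups, leaving single samples out of the profile correlations and the means over tissues were chosen after the data were seen. Not every pair of same-numbered samples of 2 tissues correlated above 0.1 in their deviations (4 of 14 at P3, 8 of 15 at P12), so numbers were not taken to pair samples. At P12 the values lean towards pairing: the median correlation was 0.109 for same-numbered and -0.023 for other pairs, against 0.045 and 0.0000509 at P3, and samples correlated best with their own number in 15 of 30 comparisons with another tissue (9 of 28 at P3). The rule that every pair lie above 0.1 does not exclude pairing. If same-numbered samples are paired, the SE of the P12 means over tissues can be too small, and the count averaged by number, 17, is the safer one. With the replicate block, P12 cord against brain passed 1 item in place of 2, and no other count of a difference changed. No value was missing, so that alternative was void, as was leaving out reference genes. The tests of P3 against P12 and their alternatives, and profile correlations of centred arrays, were not run. Array weights, robust variance, centring and a natural log base left every count of genes in the planned tests the same or within 1.5 times, though not the sign of every named gene. All genes named in the text were followed, the panel genes whatever their p included. Faint spots could not be judged without intensities.

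The cause of the following changes was not tested. With 1 fit for all tissues, the counts were 1 in P3 LDH right, 0 in P3 brain, 9 in P12 LDH left and 13 in P12 LDH right. Robust regression gave 3 in P3 LDH right, 1 in P12 LDH left, 27 in P12 LDH right and 11 in P12 brain. The plain one-sample test gave 0 in P3 brain and 2 in P12 LDH right. Testing each probe gave 2 in P3 brain and 13 in P12 LDH right, and leaving out genes with an exact 0 gave 13 in P12 LDH right and 1 for P12 cord against brain. That filter removes Ntf3, Cxcr1 and the unnamed passing probe of P12 LDH right, which each read exactly 0 on a P12 array. None of them is thus among the counts with that filter. Subtracting the mean of the other tissues gave 1 in P3 LDH right, 0 in P3 brain, 1 in P12 LDH right and 2 in P12 brain. Without arrays of low correlation the counts were 10 in P12 LDH left, 2 in P12 brain and 1 for P12 left against right. That choice of arrays favours agreement among the samples left, so these counts are no support for a change. Scaling the arrays gave 1 for P12 cord against brain. For the means over tissues, averaging by number gave 1 at P3 and 17 at P12, centring 17 at P3, and unmerged arrays 15 at P3.

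Some named genes, most of them panel genes with means near 0 that did not pass, changed sign, and the cause was not tested. Subtracting the mean of the other tissues gave reversed means in P3 LDH left Ntrk2 -0.13, Oprm1 0.21, Pdyn -0.0047, Grin1 -0.035, in P3 LDH right Grm5 0.38, Calca -0.035, Grin1 -0.0090, Grin2b 0.037, Bdnf 0.33, Il1b 0.038, Sst 0.069, Gabbr1 0.033, in P12 LDH left Oprm1 0.39, Il1b -0.11, Npy -0.35, Gabbr1 0.12, Cxcr1 0.29, in P12 LDH right Oprd1 0.14, Calca -0.024, Grin2b 0.10, Npy -0.57, Sst 0.080, Grm8 -0.016, Tacr3 0.19, and in P12 brain Cxcr1 0.22, Tacr3 0.20, Gabrr1 -0.40, Il2rb 1.10, Il1b -0.11. Robust regression gave reversed means in P3 LDH left Pdyn -0.0079, Grin1 -0.0082, Npy -0.012, in P3 LDH right Pdyn 0.0076, in P12 LDH left Grin2b -0.0011, in P12 LDH right Penk 0.14, Tac1 -0.019, Grm5 -0.017, and in P12 brain Grm5 0.080. Array weights gave reversed means in P3 LDH left Oprk1 0.13, in P12 LDH left Penk -0.049, Il6 0.10, and in P12 LDH right Penk 0.054. Centring gave reversed means in P3 LDH left Pdyn -0.014, Il1b -0.0050, and in P12 LDH right Npy -0.0063, Grm5 -0.0061. Leaving out arrays of low correlation gave reversed means in P3 LDH left Pdyn -0.0024, in P12 LDH left Penk -0.038, Calca -0.021, Grin2b -0.015, Il1b -0.021, Npy -0.22, and in the P12 mean over tissues Calca -0.00097. Unmerged arrays gave reversed means in P3 LDH left Pdyn -0.0025, and in P3 LDH right Tac1 0.024. Merging only P3 LDH left arrays 5 and 6 gave reversed means in P3 LDH right Tac1 0.024. Leaving out 1 sample gave ranges that cross 0 in P3 LDH left Pdyn -0.042 to 0.031, Grin1 -0.036 to 0.093, Oprm1 -0.22 to 0.13, Il1b -0.013 to 0.078, Oprk1 -0.51 to 0.093, Il6 -0.048 to 0.033, Npy -0.20 to 0.34, in P3 LDH right Grin2b -0.16 to 0.085, Gabbr1 -0.13 to 0.0030, Oprd1 -0.18 to 0.033, Calca -0.015 to 0.14, Tac1 -0.10 to 0.12, Pdyn -0.056 to 0.016, in P3 brain Cxcr1 -0.064 to 0.17, in P12 LDH left Il6 -0.20 to 0.13, Oprk1 -0.39 to 0.17, Penk -0.10 to 0.22, Npy -0.082 to 0.43, Grin2b -0.029 to 0.10, Il1b -0.043 to 0.40, IL12A -0.19 to 0.15, in P12 LDH right Penk -0.28 to 0.37, Il6 -0.046 to 0.28, Calca -0.031 to 0.12, Grin2b -0.20 to 0.14, Npy -0.12 to 0.12, Tac1 -0.13 to 0.34, Oprd1 -0.11 to 0.0080, Grm5 -0.048 to 0.052, and in P12 brain Grm5 -0.35 to 0.12.

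Spearman correlations moved from Pearson to 0.347 for P3 left and right cord, 0.247 for P3 left cord and brain, 0.330 for P3 right cord and brain, 0.302 for P3 left with P12 right cord, 0.118 and 0.151 for P3 right with P12 left and right cord, 0.50 for P12 left and right cord, 0.404 for P12 left cord and brain and 0.460 for P12 right cord and brain.

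Leaving out 1 sample gave counts of 0 to 1 in P3 brain, 0 to 1 in P12 LDH left (1 without replicate 4), 2 to 7 in P12 LDH right, 0 to 2 in P12 brain (2 without replicate 4), 0 to 1 for both P3 differences (1 without P3 LDH right replicate 1), 1 to 2 for P12 cord against brain, 5 to 9 and 31 to 45 for the means over tissues at P3 and P12, and 0 to 1 lists by camera in P12 LDH right (1 without replicate 4). Correlations ranged from 0.467 to 0.587 (P3 left and right cord), 0.370 to 0.471 (P3 left cord and brain), 0.428 to 0.551 (P3 right cord and brain), 0.588 to 0.723 (P12 left and right cord), 0.446 to 0.540 (P12 left cord and brain) and 0.53 to 0.574 (P12 right cord and brain). Across ages, P3 left cord gave 0.0794 to 0.134, 0.112 to 0.165 and 0.126 to 0.216 with P12 left cord, right cord and brain. P3 right cord gave 0.0266 to 0.0867, 0.0745 to 0.135 and 0.0900 to 0.149, and P3 brain -0.0094 to 0.0360, 0.0088 to 0.0700 and 0.167 to 0.209.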

Other observations

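The tests in this part were chosen after the results were seen, the means over 3 tissues and the counts of channel exchanges included. The rule for the test of sign at both ages was set down before. Its genes come from the means over 3 tissues, so that test too rests on a choice made after the results were seen.

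Averaged over the 3 tissues, 8 of 184 items passed at P3 (16 samples, limma, adjusted p under 0.05), 4 of them negative. Grm5 lay at -1.93 ± 0.32 (SE) and was negative in 16 of 16 samples. Of the 6 neurotrophin genes, 3 passed: Bdnf at -0.69 ± 0.15 and Ntf4 at -0.26 ± 0.055, each negative in 15 of 16 samples, and the Bdnf receptor Ntrk2 at 0.50 ± 0.13, positive in 14 of 16. Of the other passing genes, Htr5b, Mchr1 and Il7r had positive means and Gabrq a negative one. With arrays centred 17 items passed and with the near-identical arrays unmerged 15, the 8 among them in both. With samples of one number averaged first (n = 6), 1 gene passed, Grm5. Ntrk2 lost its call without any 1 of 9 samples, Mchr1 without any 1 of 11 and Il7r without any 1 of 13, and the count fell to 5 without LDH left replicate 1 or 5 or LDH right replicate 4 or 6.

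Averaged over the 3 tissues at P12, 36 of 185 items passed in 15 samples taken as independent, 15 positive and 21 negative, 4 of them unnamed. Tacr3 at -0.72 ± 0.10 (SE) and Cckbr at -1.21 ± 0.20 were negative in 15 of 15 samples, though the 2 Tacr3 probes differed in brain (-0.02 and -1.17), and Cxcr1 at -1.71 ± 0.22 and the mu opioid receptor Oprm1 at -0.75 ± 0.18 in 14 and 13. Of the 7 genes of the tachykinin and calcitonin gene-related peptide family, Tacr3 passed with a negative mean and Calcb (0.51 ± 0.11, positive in 15 of 15), Calcrl (0.60 ± 0.16) and Calcr (0.31 ± 0.099) with positive ones, and 3 did not pass, Calca at 0.05 ± 0.11 among them. Of the 22 glutamate receptors, with 12 positive and 10 negative means, 5 passed: Grm8, Grik1, Gria3 and Grm3 with positive means and Grik4 with a negative one. Of the 35 interleukins and receptors, with 20 positive and 15 negative means, 29 did not pass, 2 passed with positive means and 4 with negative ones, such as Il2rb at -1.56 ± 0.25 and Il23a at -1.74 ± 0.48. With samples of one number averaged first (n = 5), 17 items passed, 4 positive and 13 negative, 16 of them among the 36. Calcb, Calcrl, Calcr, Il23a, Grm8, Gria3, Grm3 and Grik4 did not pass. Calcr lost its call without any 1 of 9 samples, Grm3 without any 1 of 6, and Gria3 without LDH right replicate 5. Among 100 exchanges of channels in subsets of the samples, only the real one reached 8 items at P3 (highest other 0) and 36 at P12 (highest other 3). Each share is under 0.05 for that count taken alone, if the samples are independent of one another. With samples of one number kept together, the real count at P3 was reached in 1 of 32 exchanges (highest other 0). The share is under 0.05 for this count taken alone. It is the smallest these exchanges can give and was not adjusted for the number of counts tested. At P12 there are 16 such exchanges, too few for a share under 0.05, with counts of 36 and, as the highest other, 9.

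A candidate explanation for log ratios common to the tissues of an age is a dye or label bias, since the carrageenan sample always carried the same dye. Passing in the mean over tissues does not show a like value in each. At P12, Ntf3 passed with -1.65 in left cord, -2.58 in right cord and 0.51 in brain. The test of sign asks only about a bias fixed by the probe and equal at both ages, but it compares means of genes. Of the 40 genes that passed at either age, 70% (28) had the same sign at both, with an exact 95% interval of 53.5% to 83.4%. These genes passed with the samples of an age taken as independent. Averaged by number, only 1 item passed at P3 and 17 at P12. The interval also takes the genes as independent draws, which they are not, so it can be too narrow. The interval lies below 90%, a share chosen and not computed as the least that an equal bias would give. The platforms of the ages held different numbers of probes, 222 at P3 and 232 at P12. Several probes were averaged for 23 symbols at P3 and for 30 at P12. Probes that share a sequence entry correlated at r = -0.14 at P3 and r = -0.0092 at P12. A bias fixed by the probe thus need not give a gene equal signs at both ages. For that reason the test cannot decide whether such a bias is the whole cause, and this stays open. The interval also lies above 50%, so an equal bias may be part of the cause. A dye bias that differs between the platforms of the ages would also lower the share of equal signs, so it stays open. Over all 158 genes, the common profiles of the ages correlated at r = 0.150 ± 0.034 (jackknife SE), below the lowest r within an age of 0.459, but by rank at 0.272 ± 0.082, not below the lowest within an age of 0.247. The Pearson value was computed first and the rank measure taken after both had been seen. Pearson and rank values differ. The rank value goes with a part shared by both ages, but does not show that it is as large as within an age. A transcript change read by every probe of a transcript does not go with the probes that share a sequence entry, whose common log ratios correlated at r = -0.14 at P3 (95% bootstrap interval -0.49 to -0.013) and r = -0.0092 at P12 (-0.25 to 0.30), while the same probes correlated between tissues at 0.608 and 0.370 on average; probes of different splice forms, and the genes with 1 probe, stay open, and the P12 upper bound lies close to its comparison value. Each age had 1 platform, so batch and age cannot be told apart, and a lasting effect of injection shared by cord and brain also stays open, as untested.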
